A study of Mus musculus with 4 samples.

How the data were processed

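Group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that make type 2 cytokines, were sorted from the epididymal fat of 8-week-old male C57BL/6 mice, per the labels. Each of the 4 libraries was made from 2000 to 4000 cells, with RNA purified on micro columns and an mRNA library built by a sequencing company's standard protocol, per the labels' protocols. The sorting gate, the strandedness of the libraries and any molecular identifiers are not given in the sources used here. Groups were taken from the sample titles: 2 libraries are WT (genotype R5/+) and 2 are KO (genotype R5/+Stk11f/f, with floxed Stk11). Nothing in the labels says that the libraries come from separate animals, so p-values measure only the spread between these samples, which may be technical.

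The authors deposited 1 table of FPKM values (fragments mapped to a gene, scaled by transcript length and by the library's mapped fragments), rounded to 2 decimals, for 19088 genes with NCBI gene identifiers. Per the submitters' processing notes, Bowtie2, RSEM and DESeq2 were used with the mouse assembly GRCm38.p6; their roles, versions and settings are not given in the sources used here. The table holds no counts, so no count model was run here. FPKM carries the transcript length in its denominator and a sum over genes that differs between libraries, so a shift in a few very abundant genes, or in the length of the fragments sequenced, moves the values of other genes. RSEM shares reads among near-identical sequences, and values of members of such families (Tpsb2, Mcpt4, Lilr4b, Bcl2a1b and Bcl2a1d, and ribosomal protein genes and Fth1 with their processed copies) are uncertain to that extent. Antisense partners cannot be separated where strand was not used.

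Of the 19088 identifiers, 19034 matched the RefSeq gene table of GRCm38.p6, from which coordinates were taken (1-based). Transcript lengths came from the GENCODE M21 transcripts of the same assembly, as the median over a gene's protein-coding transcripts, and were found for 9704 of the genes tested. Depth was estimated from the steps between low FPKM values: with 200 nt subtracted from each length, the steps correspond to 18600000 and 21200000 mapped fragments in the WT libraries and 19500000 and 21100000 in the KO libraries. The match to whole fragments was partial, with step scores of 0.434 to 0.511 against at most 0.252 in 20 shuffles per library, so fragments were not recovered and no counting intervals are given. With 250 nt subtracted the scores were 0.446 to 0.515, and the estimates moved with the length subtracted. They were 17100000 at 150 nt and 19500000 at 250 nt in WT replicate 1, and 19800000 and 22600000 in KO replicate 2.

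Values were tested as log2(FPKM + 1) with limma (trend and robust variance moderation) over the 9818 genes with a mean of at least 1 FPKM in the 4 libraries, with group as the term, Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes. Means are given ± SD over the 2 libraries of a group, and fold changes with their standard errors (SE). Gene lists were tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 33 lists with at least 5 tested genes. An exact permutation test of 2 libraries against 2 cannot reach the threshold and was not used.

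Before the data were examined, the groups, the test, 40 gene lists (1081 entries, of which 1038 matched the table), the alternatives and the rule for named genes were fixed. The rule takes Stk11; the 12 called genes with the largest change in each direction whose groups do not overlap and whose mean is at least 5 FPKM, without predicted genes; up to 4 members of each list described, those past the threshold with the smallest p or else those of the highest level; and Pdcd1, Il1rl1, Il5, Il13, Gata3, Areg, Klrg1, Pparg and Ppargc1a in any case. Past the threshold was read here as over all genes or adjusted over the list alone. Adjustment over the list alone does not account for the number of lists, so genes that rose or fell on that basis only are weaker calls. Fth1, Odc1 and Pfn1, the other called genes, and some members given as markers of other cells were named after their values were seen. The lists described were also picked after the results were seen, apart from those tied to mitochondria and ILC2 identity.

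The code was tested on simulated data made for the KO and WT comparison: in 10 runs over 9818 genes, limma recovered 4% of genes changed by 1 on the log2 scale, 28.6% of those changed by 2, 60.8% by 3 and 70.2% by 4, and called 51 of 95473 unchanged genes. Simulated decreases were cut off at 0 FPKM, so in low genes they were smaller than the stated size, which lowers these recovered shares. A list shifted by -0.5 was called in 10 of 10 runs, and 1 of 320 tests of other lists was called. Genes were simulated as independent, so these list rates do not cover lists whose members vary together. In the data the correlation estimated for the ribosomal list was 0.27. Alternatives covered the pseudocount, the filter, the scaling, a fold threshold, the replicate number as a block, leaving out each library, the correlation between list members, camera on ranks and fry. With an estimated correlation, camera tests on the 2 residual degrees of freedom of the fit, so that setting has little power here whatever the correlation. Median-ratio scaling, TPM scaling (FPKM rescaled to 1 common total per library) and a length correction were added after seeing the data. The length correction removes from each library a smooth trend with transcript length and mean level together. Work was done in R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.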

Results

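RNA was measured in ILC2s sorted from the epididymal fat of mice in 2 groups of 2 libraries each, WT (R5/+) and KO (R5/+Stk11f/f). Stk11 encodes LKB1, a kinase that activates AMPK and related kinases. The study asks, by its title, how LKB1 bears on adipose ILC2 function and mitochondria. The libraries listed 9666 and 9044 genes at 1 FPKM or more in WT and 9599 and 9209 in KO. Their FPKM totals were 986027 and 1069515 in WT and 939623 and 943240 in KO, and library values correlated across genes at 0.912 or more. These correlations did not separate the groups. KO replicate 1 correlated at 0.9344 with WT replicate 1 and at 0.9313 with KO replicate 2, and the WT libraries with each other at 0.9346. Genes are not independent replicates. Errors below are SD over 2 libraries unless given as SE.

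Stk11 (gene 20869, on chromosome 10 from 80115767 to 80130679) stood at 43.1 and 39.1 FPKM in the WT libraries and at 31.9 and 16.6 FPKM in the KO libraries. Its mean was 41.1 ± 2.80 FPKM in WT and 24.2 ± 10.8 FPKM in KO (n = 2 each). The KO libraries both lay below both WT libraries, with a log2 fold change of -0.81 (SE 0.37) that did not pass the test (limma, adjusted p = 0.548). Without KO replicate 2 the log2 fold change was -0.35, and without KO replicate 1 it was -1.26. A value per gene does not separate floxed exons from the rest of the transcript. Of the 16 tested genes of the LKB1 complex, AMPK and related kinases, 0 changed over all genes or adjusted over the list alone. Prkag1, a regulatory subunit of AMPK, stood at 21.3 ± 0.50 FPKM in WT and 33.9 ± 1.32 in KO. Sik1, a kinase activated by LKB1, stood at 38.0 ± 15.4 and 30.3 ± 6.55 FPKM, and Cab39, a partner of LKB1, at 37.7 ± 2.06 and 38.0 ± 7.81 FPKM.

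Between the KO and WT libraries of sorted ILC2s, 21 of the 9818 genes tested changed (limma, adjusted p under 0.05), 16 of them higher in KO. The largest rise was in Upp1, uridine phosphorylase, from 2.52 ± 2.64 FPKM in WT to 141 ± 6.82 FPKM in KO, a log2 fold change of 5.58 (SE 0.53). Acod1, which makes itaconate in activated myeloid cells, rose from 9.05 ± 4.41 to 81.5 ± 9.37 FPKM, and Ass1, which makes argininosuccinate, from 32.8 ± 3.97 to 137 ± 0.33 FPKM. The cytokine gene Csf2, which encodes GM-CSF, fell from 15425 ± 2262 to 7552 ± 755 FPKM, a log2 fold change of -1.03 (SE 0.14). Hmgn3, a nucleosome-binding protein gene, stood at 15.3 and 20.03 FPKM in WT and at 0.08 and 0.00 FPKM in KO; its log2 fold change was -4.15, and -7.03 with a pseudocount of 0.1.

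Among the other genes that rose, Cables1 stood at 0.24 ± 0.22 FPKM in WT and 17.4 ± 2.84 in KO, and Inka1 at 3.25 ± 1.23 and 28.7 ± 0.21 FPKM. Prr15 rose by a log2 fold change of 2.60 (SE 0.37) and Hey1, a transcriptional repressor downstream of Notch, by 2.52 (SE 0.33). Surface receptor genes that rose were Plaur, the urokinase receptor, from 104 ± 20.4 to 391 ± 80.4 FPKM, and Tnfrsf9, the costimulatory receptor 4-1BB, from 80.3 ± 28.8 to 289 ± 4.14 FPKM. Lilr4b, an immunoglobulin-like receptor gene, rose from 556 ± 122 to 1459 ± 154 FPKM. Apoe, an apolipoprotein, rose from 80.9 ± 15.9 to 308 ± 61.5 FPKM. The mast cell protease genes Tpsb2 and Mcpt4 rose by log2 fold changes of 1.55 (SE 0.19) and 1.20 (SE 0.15). A further 3 genes are named because they were called, chosen after their values were seen. These are Fth1 (ferritin heavy chain, log2 fold change 1.18, SE 0.14), Odc1 (polyamine synthesis, 1.14, SE 0.16) and Pfn1 (actin binding, 1.03, SE 0.15). Of the other genes that fell, Acbd7 went from 576 ± 59.7 to 216 ± 1.53 FPKM. Atp5md, a small subunit of ATP synthase, fell from 3510 ± 56.3 to 1689 ± 27.3 FPKM, and the ribosomal protein gene Rps27 from 20548 ± 2541 to 11072 ± 535 FPKM.

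**Figure D1:**
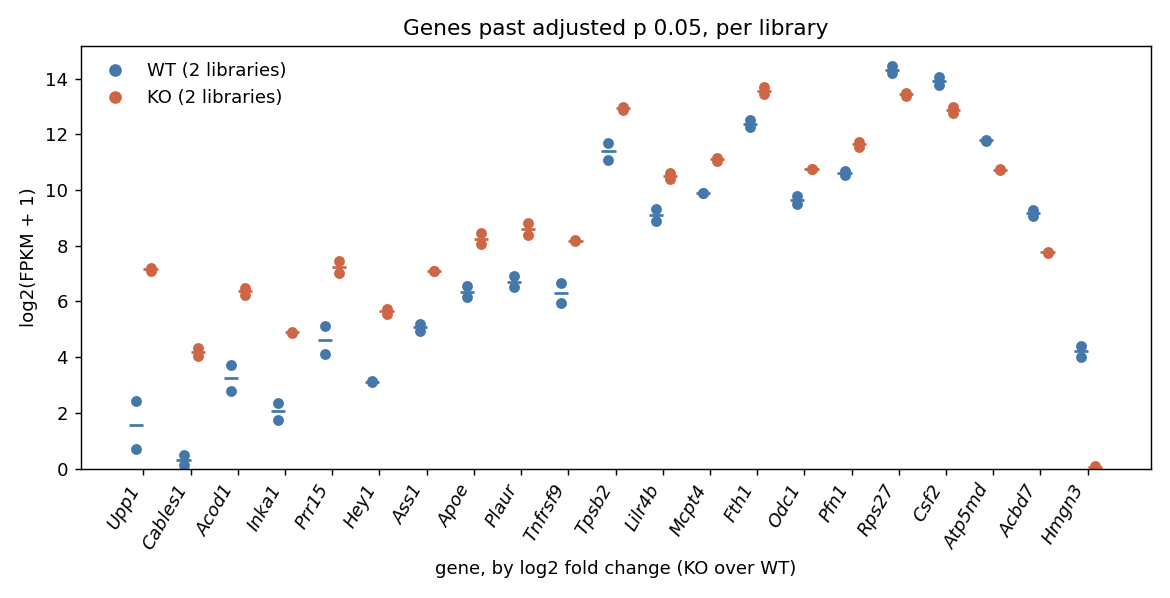
Each point is the log2(FPKM + 1) of 1 library for the 21 genes past the threshold (WT blue, KO orange, 2 libraries each), with short lines at the group means. The KO points lie apart from the WT points in all 21 genes, by log2 fold changes from 5.58 (Upp1) to -4.15 (Hmgn3).

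In all 21 genes, both KO libraries lay outside the range of the WT libraries. Over all genes tested this held for 39.13%, where chance gives 33.33%. With the groups so apart, leaving out 1 library or changing the pseudocount or filter cannot turn a gene's direction. The directions given below are no support in those settings. The adjusted p-values of the 21 genes from limma lay between 0.0318 and 0.0475, and 901 genes had an unadjusted p under 0.05. With the replicate number as a block, which the labels do not tie to a pairing, 0 genes passed (limma, smallest adjusted p 0.0534). The calls ended (0 genes past the threshold) with a pseudocount of 0.1, without a filter, with quantile normalization, with the length correction and when any 1 library was left out, and median-ratio scaling left 1; in each of these the 21 genes kept their direction.

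On GRCm38.p6, the genes that rose lie as follows: Upp1 (gene 22271) on chromosome 11 from 9118008 to 9136170, Cables1 (gene 63955) on chromosome 18 from 11839274 to 11945627, Acod1 (gene 16365) on chromosome 14 from 103047012 to 103056573 and Inka1 (gene 68176) on chromosome 9 from 107984223 to 107985916. The annotation places Prr15 (gene 78004) on chromosome 6 from 54326756 to 54343436, Hey1 (gene 15213) on chromosome 3 from 8663359 to 8667038, Ass1 (gene 11898) on chromosome 2 from 31470270 to 31520670 and Apoe (gene 11816) on chromosome 7 from 19696244 to 19701310. It places Plaur (gene 18793) on chromosome 7 from 24460937 to 24475970, Tnfrsf9 (gene 21942) on chromosome 4 from 150920155 to 150946104, Tpsb2 (gene 17229) on chromosome 17 from 25366308 to 25368096 and Lilr4b (gene 14727) on chromosome 10 from 51480612 to 51486329. It also places Mcpt4 (gene 17227) on chromosome 14 from 56059744 to 56062310, Fth1 (gene 14319) on chromosome 19 from 9980600 to 9985111, Odc1 (gene 18263) on chromosome 12 from 17544808 to 17551502 and Pfn1 (gene 18643) on chromosome 11 from 70651844 to 70656799. Of the genes that fell, it places Hmgn3 (gene 94353) on chromosome 9 from 83109942 to 83147358, Acbd7 (gene 78245) on chromosome 2 from 3332814 to 3340998 and Atp5md (gene 66477) on chromosome 19 from 47083471 to 47090647. It puts Csf2 (gene 12981) on chromosome 11 from 54247270 to 54249899 and Rps27 (gene 57294) on chromosome 3 from 90212667 to 90213648.

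Genes that define ILC2s did not pass the test as a list. Over 26 tested genes of ILC2 identity, the median log2 fold change was 0.04 (camera, limma, adjusted p = 0.641). Gata3, the master regulator of the lineage, stood at 476 ± 76.2 FPKM in WT and 463 ± 64.3 in KO, and Il1rl1, the IL-33 receptor, at 270 ± 28.1 and 217 ± 2.74 FPKM. Klrg1, a maturation marker, stood at 568 ± 11.5 and 578 ± 106 FPKM, and Pparg, a nuclear receptor of adipose-tissue ILC2s, at 58.3 ± 21.6 and 60.6 ± 14.0 FPKM. The costimulatory receptor gene Icos rose adjusted over the list alone, from 128 ± 10.9 to 276 ± 5.59 FPKM, as the 1 gene of this list to pass; 0 passed over all genes.

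Of 22 tested cytokine and effector genes, 4 fell adjusted over the list alone, 1 of them over all genes. These were Csf2, Ccl1 (a chemokine, 3486 ± 334 FPKM in WT and 1856 ± 424 in KO), Tnfsf8 (CD30 ligand, 8.16 ± 2.81 and 0.33 ± 0.40) and Tnfsf11 (RANKL, 103 ± 9.93 and 42.7 ± 4.02). The median log2 fold change of the list was -0.15, with 16 of 22 genes negative, and camera did not call it (limma, adjusted p = 0.202). By fry, which asks whether members change in either direction and does not compare them with other genes, it passed (limma, adjusted p = 0.0152). Il5 stood at 670 ± 112 FPKM in WT and 646 ± 45.2 in KO, Il13 at 68.6 ± 9.14 and 61.6 ± 13.9, and Areg, which encodes amphiregulin, at 1017 ± 280 and 912 ± 195 FPKM; these 3 genes did not pass.

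Of 20 tested inhibitory receptor and exhaustion-linked genes, 0 changed over all genes. Adjusted over the list alone, which does not account for the number of lists, 2 rose and 1 fell. Pdcd1, which encodes the inhibitory receptor PD-1, rose from 52.5 ± 26.6 to 172 ± 6.67 FPKM, a log2 fold change of 1.79 (SE 0.35; limma, adjusted p = 0.127 over all genes and 0.0118 over the list). Nt5e, the ectoenzyme CD73, rose from 11.6 ± 7.41 to 49.8 ± 7.09 FPKM, and the nuclear receptor gene Nr4a3 fell from 373 ± 18.5 to 227 ± 17.6 FPKM. The list as a whole had a median log2 fold change of -0.08 (camera, limma, adjusted p = 0.734).

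Nuclear genes of the electron transport chain and ATP synthase fell as a list: 60 of 77 had a negative log2 fold change, with a median of -0.22 (camera, limma, adjusted p = 0.0425). With an estimated correlation, a setting of little power on 2 residual degrees of freedom, the adjusted p = 0.859 (camera, limma). No single member changed, 0 of 77 over all genes and 0 adjusted over the list alone; Atp5md is not on the list. Among the members of the highest level, Uqcrh of complex III stood at 1995 ± 103 FPKM in WT and 1475 ± 112 in KO, Cox6b1 at 2292 ± 19.7 and 2060 ± 222, Cox6a1 at 1879 ± 189 and 1689 ± 184, and Cox8a at 1617 ± 100.5 and 1473 ± 149. With quantile normalization Cox6b1, Cox6a1 and Cox8a had positive log2 fold changes. The list test lost its call without WT replicate 2 (median -0.14, adjusted p = 0.651, limma) and without KO replicate 1 (0.548), and with a pseudocount of 0.1, quantile normalization (median -0.13), scaling without the 20 highest genes (-0.12), median-ratio scaling (-0.20), TPM scaling (-0.10) and the length correction (-0.15), at adjusted p of 0.0550 to 0.334 in these 6 settings. Genes encoded in mitochondrial DNA were not analysed here, because no entry of their list matched a gene of the deposited table.

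Camera called no other mitochondrial list. The TCA cycle (20 genes, 0 changed over all genes or adjusted over the list alone) had a median log2 fold change of -0.14 (camera, limma, adjusted p = 0.495), with Mdh2 at 226 ± 9.56 FPKM in WT and 274 ± 26.7 in KO. Biogenesis, fusion and fission genes (21 genes, 0 changed by either count) had a median of 0.01 (camera, limma, adjusted p = 0.734), and the coactivator gene Ppargc1a was at 0.09 and 0.19 FPKM in WT and 0.06 and 0.13 in KO, under the filter. Mitophagy and autophagy genes (33 genes, 0 changed by either count) had a median of -0.10 (camera, limma, adjusted p = 0.822), with Gabarap at 267 ± 7.06 and 377 ± 17.4 FPKM. Among 26 genes of fatty acid uptake and oxidation, 0 changed over all genes and 2 fell adjusted over the list alone, the fatty acid transporter gene Cd36 (6.31 ± 1.98 to 0.31 ± 0.35 FPKM) and Etfdh, which passes electrons from fatty acid oxidation to the chain (19.8 ± 3.02 to 5.26 ± 1.40 FPKM). The median of that list was 0.20 while its mean was -0.03 and camera gave a downward direction (limma, adjusted p = 0.876). By fry in either direction that list passed (limma, adjusted p = 0.0448).

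Genes of the cytosolic ribosome fell together: all 72 tested members had a negative log2 fold change, with a median of -0.53 (camera, limma, adjusted p = 2.49e-13). With an estimated correlation, a setting of little power on 2 residual degrees of freedom, the adjusted p = 0.859 (camera, limma). Of the 72, 1 fell over all genes (Rps27) and 52 adjusted over the list alone, among them Rpl35 (9473 ± 402 FPKM in WT, 5576 ± 416 in KO), Rps14 (9483 ± 86.3 and 6005 ± 192) and Rps18 (5559 ± 373 and 3296 ± 189). Ribosomal protein genes took 19.3% and 18.5% of all FPKM in the WT libraries and 14.2% and 13.5% in the KO libraries. The direction held under each scaling tried and with each library left out, with medians from -0.59 to -0.33. TPM scaling (each library's FPKM rescaled to 1 common total) moved the median log2 fold change of all genes by 0.11, and the ribosomal median was then -0.41.

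Outside these lists the median also varied with transcript length, lowest at both ends, and this was not tested. Among other genes with a mean of at least 100 FPKM, the median log2 fold change was -0.30 for 30 genes of up to 500 nt, -0.15 for 149 genes of over 500 and up to 700 nt and 0.07 for 180 genes of over 1000 and up to 1500 nt. It was -0.35 for 24 genes over 4000 nt.

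**Figure D2:**
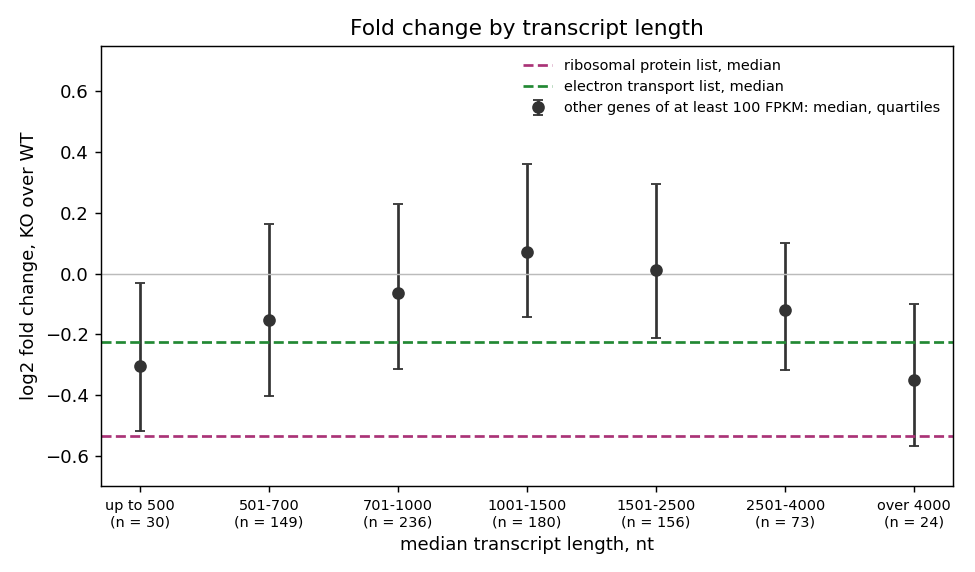
Points show the median log2 fold change (KO over WT) of genes with a mean of at least 100 FPKM outside the ribosomal and electron transport lists, by transcript length in nt, with bars from the lower to the upper quartile. Dashed lines mark the medians of the ribosomal list (-0.53) and the electron transport list (-0.22).

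Glycolysis genes rose as a list, with 18 of 21 tested members at a positive log2 fold change and a median of 0.31 (camera, limma, adjusted p = 0.0351). With an estimated correlation, a setting of little power on 2 residual degrees of freedom, the adjusted p = 0.859 (camera, limma). Over all genes or adjusted over the list alone, 0 members changed. Aldoa stood at 340 ± 23.0 FPKM in WT and 505 ± 108 in KO, Eno1 at 138 ± 3.68 and 199 ± 44.9, Gapdh at 628 ± 72.5 and 735 ± 192, and Ldha at 915 ± 36.5 and 951 ± 37.6. The call ended without WT replicate 1 (median 0.44, adjusted p = 0.0867, limma), WT replicate 2 (0.28, 0.134) or KO replicate 1 (0.12, 0.265), and with the filter of 5 FPKM in 2 libraries (0.26, 0.114). Without KO replicate 2 the list stayed called, with a median of 0.67. Among 20 HIF-1 targets, 0 changed over all genes and 1, the oxygen sensor gene Egln3, rose adjusted over the list alone, from 2.99 ± 2.11 to 24.9 ± 5.20 FPKM.

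Immediate-early and dissociation-stress genes, which respond to handling of tissue as well as to signals, rose as a list of 28 with a median log2 fold change of 0.27 (camera, limma, adjusted p = 0.0425). With an estimated correlation, a setting of little power on 2 residual degrees of freedom, the adjusted p = 0.859 (camera, limma). Of these, 0 changed over all genes and 5 rose adjusted over the list alone: the heat shock genes Dnajb1 (72.8 ± 2.58 to 150 ± 5.86 FPKM), Hsp90aa1 (235 ± 0.19 to 390 ± 21.1) and Hspa8, and the early response genes Egr1 (52.9 ± 9.51 to 133 ± 42.4) and Ier3 (45.2 ± 18.9 to 99.3 ± 5.16, a log2 fold change of 1.18, and 0.75 without WT replicate 2). The call ended without WT replicate 1 (median 0.33, adjusted p = 0.351, limma), KO replicate 1 (0.12, 0.227) or KO replicate 2 (0.38, 0.0700), with a pseudocount of 0.1 (0.0784) and with camera on ranks (0.0534).

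Markers of mast cells, basophils and eosinophils rose as a list in KO, with 10 of 11 tested genes higher and a median log2 fold change of 1.12 (camera, limma, adjusted p = 3.53e-04). With an estimated correlation, a setting of little power on 2 residual degrees of freedom, the adjusted p = 0.859 (camera, limma). Tpsb2 and Mcpt4 rose over all genes, and 7 of the 11 rose adjusted over the list alone, including Fcer1a, a chain of the IgE receptor (346 ± 16.2 to 875 ± 203 FPKM), and the mast cell chymase gene Cma1 (6272 ± 919 to 13402 ± 5482 FPKM, a log2 fold change of 1.04, and 0.61 without KO replicate 2). The list stayed called with each library left out, but its median was 0.70 without WT replicate 2 and also 0.70 without a filter on low values. Kit stood at 74.0 ± 10.8 and 85.4 ± 3.45 FPKM. In total, 8 mast cell genes picked after the values were seen took 1.59% and 1.24% of FPKM in WT and 2.61% and 4.09% in KO. Haemoglobin genes of red blood cells took 5.40% and 7.86% in WT and 7.18% and 2.83% in KO. Both shares apply to all of the gene groups described above and to the 21 called genes. Which cells in the libraries these genes came from was not tested.

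**Figure D3:**
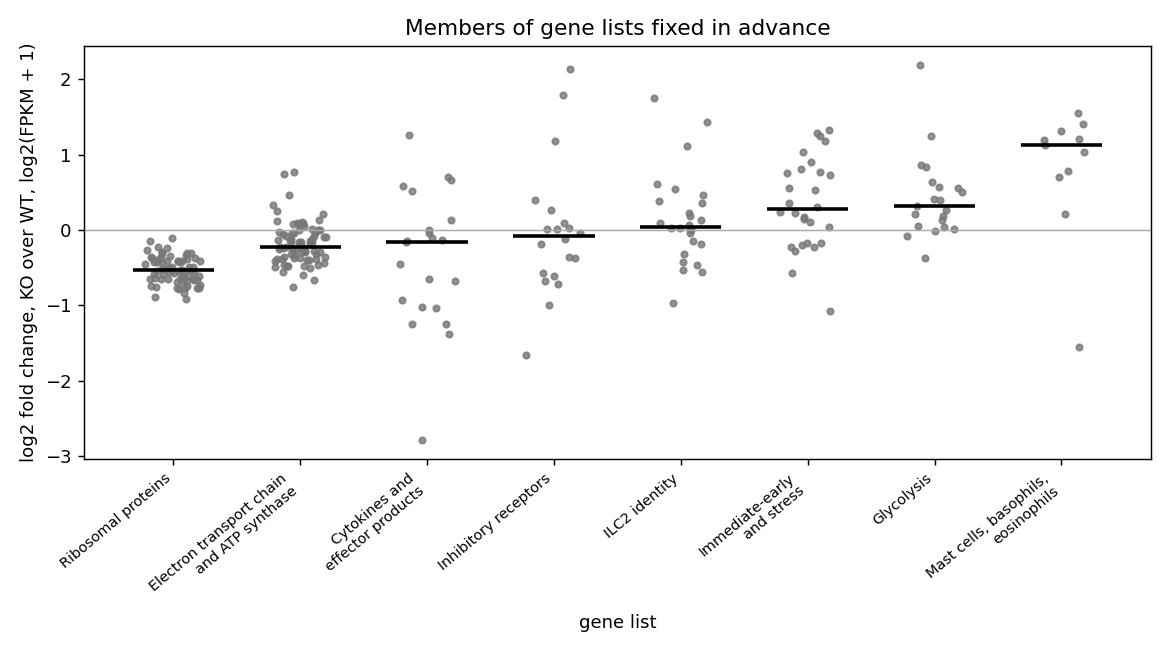
Each point is the log2 fold change (KO over WT, log2(FPKM + 1) scale) of 1 tested gene, by gene list, and the black line is the list's median. The ribosomal list lies below 0 throughout (median -0.53) and 10 of 11 mast cell, basophil and eosinophil genes lie above 0.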

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

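Median-ratio scaling, TPM scaling and the length correction were chosen after seeing the data. The count of 21 changed genes was 20 with a fold threshold of 1 (log2), 20 with at least 5 FPKM in 2 libraries, 24 (20 higher) without the 20 highest genes in the scaling and 23 (19 higher) with TPM scaling. It was 0 with a pseudocount of 0.1 (limma, smallest adjusted p 0.0501, 874 genes at an unadjusted p under 0.05), without a filter (0.394, 947), with quantile normalization (0.0639, 890) and with the length correction (0.0692, 872), and 1 (1 higher, 0 lower) with median-ratio scaling. Leaving out any 1 library gave 0 genes (limma, smallest adjusted p 0.0612 to 0.332, 528 to 896 genes at an unadjusted p under 0.05); the arm left with 1 library is assumed to vary like the other. The 21 genes kept their direction in all of these settings. As their groups do not overlap, this was fixed in advance for the pseudocount, the filter and any left-out library. The cause of these losses was not tested, except that without a filter more genes (18357) are tested. With the replicate number as a block, which the labels do not tie to a pairing (correlation of the deviations 0.025), limma called 0 genes (smallest adjusted p 0.0534, 1012 at an unadjusted p under 0.05) and 5 lists. Stk11 stayed negative and short of the threshold in every setting (-0.35 to -1.26 with 1 library left out), and the ILC2 identity list stayed short of it with medians of 0.02 to 0.17.

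The count of 5 lists was 3 with a pseudocount of 0.1, 3 to 4 with 1 library left out, 0 with an estimated correlation (smallest adjusted p 0.859), 0 by fry in 1 direction (0.385) and 7 by fry in either direction (ribosomal, cytokine, MHC class II, apoptosis, stromal, migration and fatty acid lists). The electron transport list median was -0.23 with a pseudocount of 0.1, -0.13 with quantile normalization, -0.12 without the 20 highest genes, -0.20 with median-ratio scaling, -0.10 with TPM scaling, -0.15 with the length correction and -0.30 to -0.14 with 1 library left out, and -0.22 with an estimated correlation and by fry; it was not called in these, except without WT replicate 1 or KO replicate 2. The ribosomal and mast cell lists stayed called in 13 of 13 settings of the gene fit (medians -0.59 to -0.33 and 0.70 to 1.26), glycolysis (0.12 to 0.67) and the immediate-early list (0.12 to 0.40) in 9 of 13, and the electron transport list in 5 of 13.

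Of 90 named genes with a fit, 70 kept their sign throughout, called genes included. Among those that did not pass, quantile normalization turned Il5 (0.029), Gata3 (0.039), Cox6b1 (0.14), Cox6a1 (0.099), Cox8a (0.047), Pdhb (-0.028) and Gabarapl2 (0.024). Scaling without the 20 highest genes turned Il5 (0.056), Gata3 (0.063), Fis1 (0.021), Phb (0.088), Gabarapl2 (0.070) and Cab39 (0.095). TPM scaling turned Il5 (0.080), Gata3 (0.087), Fis1 (0.045), Phb (0.11), Gabarapl2 (0.094), Map1lc3b (0.014) and Cab39 (0.12). Median-ratio scaling turned Phb (0.011) and Cab39 (0.017), and the length correction Pdhb (-0.039). With 1 library left out, the log2 fold change ranged for Il5 from -0.22 to 0.13, Il13 from -0.39 to 0.064, Gata3 from -0.20 to 0.13, Areg from -0.43 to 0.14, Klrg1 from -0.17 to 0.20, Pparg from -0.29 to 0.47, Gapdh from -0.062 to 0.48, Pdhb from -0.080 to 0.089, Mff from -0.69 to 0.38, Phb from -0.16 to 0.14, Gabarapl2 from -0.18 to 0.12, Map1lc3b from -0.35 to 0.13, Cab39 from -0.21 to 0.20, Sik1 from -0.69 to 0.14, Cd79b from -0.20 to 2.12 and Fabp4 from -2.86 to 3.52. Among genes that passed over all genes or a list, a pseudocount of 0.1 moved Hmgn3 to -7.03, Tnfsf8 to -4.62, H2-DMb1 to -4.96, Cd36 to -4.27, Cd79a to 4.37 and Blnk to 4.11, over 1.5 times the main value. The planned count models (DESeq2, its size factors, limma-voom, and FPKM beside counts) were not run because the table holds no counts. The cause of the turns was not tested. With 2 libraries per group, simulated changes of 1 on the log2 scale were recovered in 4% of genes, so a gene short of the threshold is not shown to be unchanged.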

Other observations

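Further lists held genes that passed adjusted over the list alone, and of those named here Tnfrsf9 alone passed over all genes. The adjustment over a list does not account for the number of lists. Among migration and residency genes (22 tested, median log2 fold change 0.14, camera in limma, adjusted p = 0.372, and 0.0152 by fry in either direction), Klf2 rose from 23.1 ± 0.17 to 63.8 ± 8.69 FPKM, Cxcr4 from 23.4 ± 2.12 to 50.8 ± 1.72 and Cd69 from 225 ± 32.6 to 388 ± 59.0, and the chemokine receptor gene Ccr2 fell from 444 ± 73.8 to 209 ± 85.6 (log2 fold change -1.13, and -0.71 without KO replicate 2). Among cell-cycle inhibitors and p53 targets (18 tested), Trp53 rose from 7.86 ± 2.81 to 28.4 ± 6.04 FPKM and Cdkn1a from 251 ± 51.3 to 530 ± 194 (log2 fold change 1.04, and 0.66 without KO replicate 1), while Cdkn2c fell from 16.6 ± 1.24 to 5.82 ± 0.29. The antiapoptotic genes Bcl2a1b and Bcl2a1d, near-identical copies, fell from 574 ± 166 to 216 ± 98.4 and from 1548 ± 273 to 703 ± 328 FPKM (Bcl2a1d log2 fold change -1.21, and -0.72 without KO replicate 1). Of 27 genes of calcium and antigen-receptor-like activation, Tnfrsf9 and Egr1 rose.

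H2-Ab1, an MHC class II chain, fell adjusted over the list alone from 19.97 ± 12.5 to 0.82 ± 0.63 FPKM and H2-DMb1 from 5.78 ± 3.77 to 0.07 ± 0.03. The cytotoxic genes Gzmb and Klrk1 rose on that basis, from 130 ± 99.9 to 419 ± 116 and from 2.44 ± 1.72 to 15.5 ± 1.39 FPKM (Gzmb log2 fold change 1.90, and 1.03 without WT replicate 2). Of 4 tested B and plasma cell genes, Cd79a and Blnk rose on the same basis, from 0.84 ± 1.20 to 8.90 ± 3.20 and from 0.15 ± 0.21 to 3.36 ± 0.07 FPKM, and Cd79b stood at 3.51, 0.19, 9.07 and 1.01 FPKM in WT replicates 1 and 2 and KO replicates 1 and 2. Jchain, a plasma cell gene, was listed at 230 FPKM in WT replicate 1 and at 0.00 in the 3 other libraries, and Fabp4, an adipocyte gene, at 139, 0.68, 15.8 and 21.1 FPKM in WT replicates 1 and 2 and KO replicates 1 and 2.

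All tests in the paragraphs that follow were chosen after the results they bear on had been seen. All 72 ribosomal protein genes were lower in KO. A trend with transcript length as the whole cause is argued against, as far as the lengths used describe it. After a trend with length and mean level was fitted on genes outside the list and removed, the median was -0.465 (quartiles -0.57 and -0.31, before -0.66 and -0.41). All 72 genes stayed lower and the list stayed called (limma, camera adjusted p = 9.78e-11). Among 10000 random lists matched on length and level, the typical median was -0.15, and the uncorrected one of this list lay at percentile 0. Those lists were drawn gene by gene, while the correlation estimated for the ribosomal list was 0.27. Their spread may therefore be too narrow and the percentile too extreme. Only 30 other genes of up to 500 nt had a mean of at least 100 FPKM. Lengths are medians over annotated transcripts, so the correction may have removed too little. A difference in genotype, or in the state of the cells at sorting, stays open and untested. The call was made with the preset correlation and ended with an estimated one, a setting in which 0 lists were called. That loss is not due to correlation alone, because the estimated setting tests on only the 2 residual degrees of freedom of the fit. For the immediate-early list the estimate was -0.024, under the preset 0.01, yet the unadjusted camera p (limma) went from 0.00644 to 0.0917.

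The electron transport list behaved otherwise. With the same correction its median went from -0.225 (quartiles -0.38 and -0.03, 60 of 77 genes lower) to -0.147 (quartiles -0.29 and 0.01, 56 of 77 lower), and the call ended (limma, camera adjusted p = 0.238); the median shrank and the quartile range narrowed slightly, and why the call ended was not tested further. Among 10000 random lists matched on length and level, its uncorrected median lay at percentile 1.25, and the typical median of such lists was -0.10. These were also drawn gene by gene, while the correlation estimated for the list was 0.17, so the percentile may be too extreme. Transcript length or expression level, which the correction and the matching take together, may therefore account for part of this list's difference. A difference between the genotypes in these genes cannot be told apart from such trends here. The 2 libraries per group leave the size of the remainder open.

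Mast cell and basophil genes were higher in KO, and a trend with transcript length is argued against, since the median was 1.12 after the correction as before it. A larger share of mast cell RNA in the KO libraries would raise by 1 common factor those genes that no other cells in the sample express. The list also holds basophil and eosinophil markers, and whether other cells express its genes was not tested. The 10 genes of at least 10 FPKM had log2 fold changes from 0.21 for Kit to 1.55 for Tpsb2. An approximate chi-square test over these genes, the first one run, gave p = 0.00754 against 1 factor. In 6.97% of 100000 draws with the heavier-tailed errors of so few libraries, the fold changes differed as much. Errors were drawn as independent between genes, while the correlation estimated for the list was 0.463. Errors shared between genes would lower such a share, so the spread does not decide. Without Kit, which is also on the ILC3 list and was left out after the first result had been seen, 55.6% of draws differed as much, around a common log2 fold change of 1.22. Mast cell RNA may be a source, but ratios to Tpsb2 changed by up to 2.05 times between libraries of a group (Cpa3 in KO), so this and a change of expression within ILC2s cannot be told apart. The sorting gate, which would bear on the question, is not given in the labels.

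The count of 21 changed genes was also set against the other ways of splitting 4 libraries into 2 and 2. Of 3 splits, 1 gave as many genes, the real one, and the highest of the others gave 0; 3 splits are too few for a share under 0.05.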
